A study of Mus musculus with 2 samples.

How the data were processed

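The series holds ChIP-seq of trimethylated lysine 4 of histone H3 (H3K4me3), a mark found at the start sites of transcribed genes, in neural tube tissue of B6NCrl mouse embryos at 15.5 days. Each of the 2 libraries was a biological replicate made from a pool of embryos of both sexes, 78 in replicate 1 and 62 in replicate 2. Both libraries belong to 1 group and there was no second condition, so the comparisons are between the libraries, between kinds of genomic position and between lists of genes.

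The authors deposited peak lists in narrowPeak form on the mouse build mm10, per the labels. Per the records deposited beside the lists, each library's own list was called on that library against its own control alignment, and a pooled list was called on both libraries together. A replicated list was deposited too. Each of its 25089 peaks is also a peak of the pooled list of 31306. Of these, 23503 overlapped a peak of each library by at least 50% of either peak, and 0 of the 6217 pooled peaks left out of it did. The rule by which the other 1586 entered is not given in the sources used here, nor are the aligner, the peak caller and their versions. The authors' signal value of each peak is given as deposited. Its formula is not given in the sources used here. It was used to describe, rank or filter peaks within a list, and in a rank correlation between the libraries. It was also used to compare gene lists with random lists within the replicated list. The plan had called it fold enrichment, and the comparisons planned with it were kept. The deposited −log10 p and −log10 q of each peak are the authors' too. The p was not used, and the q served for 1 alternative threshold and for counts of weak peaks. The lists hold no read counts, so the depth of the libraries is unknown and no counting interval can be given. The lists hold some peaks with q above 0.05, 927 in replicate 1, 626 in replicate 2 and 10 in the replicated list.

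Genes and transcript start sites were taken from GENCODE release M21 on GRCm38, the same build as mm10. Chromosome lengths of the reference were checked against the peaks: on 21 chromosomes, 0 peaks ran past a chromosome end. The background was the 21945 protein-coding genes on chromosomes with replicated peaks. A gene was counted as occupied when a peak lay within 1000 bp of any of its annotated transcript start sites. Peaks separated by up to 1000 bp were merged into domains, and a gene's promoter domain was the widest within 1000 bp of a start site. Domains among the widest 5% of genes were called broad, which meant wider than 5405 bp. A gene was called CpG-rich when any start site had a GC fraction of at least 0.5 and an observed/expected CpG ratio of at least 0.6 over 500 bp on either side. CpG content, repeats and repeated words were read from the soft-masked GRCm38 sequence. Peaks outside promoters were placed in exons, introns or intergenic sequence in that order.

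The 26 gene lists, the tests and the alternatives were fixed before the data were examined. All symbols matched the annotation, 1 of them (Drgx, annotated as Prrxl1) through an older name. Occupancy of a list was compared with all other protein-coding genes by Fisher's exact test, two-sided. The same test compared the broad domains of its occupied members with those of the other genes with a promoter domain. The median domain width of a list with at least 5 occupied members was compared with 100000 random lists of the same size by a two-sided permutation test. The smallest p these permutations can give is 2e-05. All p-values were adjusted by the Benjamini-Hochberg method over the 26 lists for occupancy and the 19 lists tested for width and broad domains, with a threshold of 0.05. Genes are not independent replicates, and the tests describe these libraries. Where replicate error is given, it is the value in each library or the mean ± SD of both. Other widths are from the replicated list alone, and the libraries can differ from them. The procedure was tested on simulated data, lists of 20 genes drawn from 21945. It called 0% of 20 unchanged lists, 95% of lists occupied at a rate of 0.25 and 85% and 95% of lists with domains widened 1.5 and 2 times. Each simulated gene had its own domain, with occupancy and width drawn independently. The 20 lists of a kind were adjusted together. The rates thus do not hold for lists with shared domains, such as Hox, or for the mixed set of 26 lists.

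The genes named are, for each list, the members with the widest domains (2 per list) and the first unoccupied members in alphabetical order (2 per list), then up to 4 genes of each of the 10 widest domains, the 5 with the highest promoter signal value and the 5 with the highest signal value among those occupied in 1 library alone, for each library. Peaks farther than 10000 bp from any start site were named by the same kind of rule, the 5 with the highest signal value. Some genes that share a domain with a named gene are given with it. Any other gene named outside this rule was chosen after its values were seen, and this is said where it is named. Alternatives were peaks with −log10 q of at least 10 or a signal value of at least 5, the pooled list, each library alone, windows of 500 and 2500 bp, 1 start site per gene, gaps of 0 and 3000 bp, CpG-rich genes alone, each domain counted once, broad domains as the widest 10%, and overlaps of 50%. RefSeq transcript starts on GRCm38, and each domain counted once in the Hox groups, were added as alternatives after the data were examined. Overlaps were computed with bedtools 2.31.1 and all else in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Files other than the peak lists were not used for values.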

Results

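H3K4me3 was mapped by ChIP-seq in neural tube from mouse embryos of 15.5 days, in 2 biological replicates, each a pool of embryos. Replicate 1 had 29903 peaks covering 39.1 Mb and replicate 2 had 30040 peaks covering 40.0 Mb. The authors' replicated list held 25089 peaks covering 41.9 Mb, with a median width of 1433 bp. Read depth is unknown. Coordinates are on mm10.

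The first comparison concerned how far the libraries shared their peaks. Of the peaks of replicate 1, 86.5% were overlapped by at least 1 bp by a peak of replicate 2, and of those of replicate 2, 84.7% by a peak of replicate 1. The shared bases made up 83.4% of the bases covered in either library. The 4026 peaks seen in replicate 1 alone were narrow and weak, with a median width of 228 bp and a median signal value of 2.90, against 1243 bp and 18.2 for shared peaks. The 4608 peaks of replicate 2 alone had a median width of 238 bp and a median signal value of 3.03, against 1310 bp and 20.4.

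At the level of genes the libraries differed little. A promoter peak was present at 14641 protein-coding genes in replicate 1 and 14666 in replicate 2, and 14539 genes had one in both. Across these genes, which are not independent replicates, Spearman's rho between the libraries was 0.933 for domain width and 0.745 for signal value. Of the 102 genes occupied in replicate 1 alone, 99 had a signal value under 5. The highest values among the 102 were 46.6 at Sftpc, a lung surfactant gene whose domain also lies within 1000 bp of a start site of Bmp1, and 30.4 at Rbp1, a retinol-binding protein. They were followed by Hist1h4n at 5.51, Acsbg1 at 4.79 and Tcf21 at 4.68. Of the 127 genes occupied in replicate 2 alone, 121 had a signal value under 5, and the highest values were 36.7 at Pdia2, 34.9 at B3gnt4, 19.3 at Tsks, 15.4 at Igfn1 and 10.2 at Gm11444. In 18 and 23 of these genes the other library had a peak within 2500 bp. No peak of replicate 1 without an overlapping peak in replicate 2 had a signal value above 6.65, and none of replicate 2 without one in replicate 1 above 7.15. The peaks at Sftpc and Rbp1 and at the 5 genes named for replicate 2 were thus shared, and in the other library they lay outside the 1000 bp window.

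Most of the mark lay at gene promoters. Of the replicated peaks, 67.6% lay within 1000 bp of an annotated start site, with a median width of 1985 bp and a median signal value of 41.2. The share was 62.1% in replicate 1 and 61.6% in replicate 2. Of the rest, 5.38% of all peaks lay in exons, 13.1% in introns and 13.9% between genes, and peaks outside promoters had a median width of 575 bp and a median signal value of 4.73. A replicated promoter peak marked 14609 of 21945 protein-coding genes (66.6%). CpG content divided the genes: 11139 of 11242 CpG-rich genes (99.1%) were marked, against 32.4% of the 10703 others. The highest promoter signal values belonged to Rpsa, a ribosomal protein gene, at 71.3, Uqcrfs1, a subunit of respiratory complex III, and Aamdc, Rsf1 and Tfip11. Aamdc and Rsf1 shared 1 domain at chromosome 7, 97578357 to 97581824.

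In the pan-neuronal list and the list of progenitors and neurogenesis, nearly every gene was marked, and domains were wide. All 24 pan-neuronal genes were occupied (adjusted p = 0.00027, Fisher's exact test), with a median domain of 5157 bp against 2382 bp for all marked genes. The median was 5005 bp in replicate 1 and 5122 bp in replicate 2, and the permutation test gave an adjusted p = 6.3e-05 (raw p = 2e-05, the smallest the permutations can give). Of the 24, 10 had a broad domain (adjusted p = 6e-07, Fisher's exact test). The widest were at Myt1l, a neuronal zinc finger factor, with 13818 bp (13731 ± 13.4 bp in the libraries, SD, n = 2), and at Elavl4, a neuronal RNA-binding protein, with 11779 bp (11616 ± 67.9 bp in the libraries, SD, n = 2). Of 21 genes of progenitors and neurogenesis, 20 were occupied (adjusted p = 0.0067) with a median of 4854 bp (4302 and 4679 bp in the libraries, adjusted p = 6.3e-05, permutation test). Sox2, a factor of neural stem cells, had 8978 bp and the Notch target Hes1 had 8409 bp, while Neurod4 had no promoter peak.

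**Figure D1:**
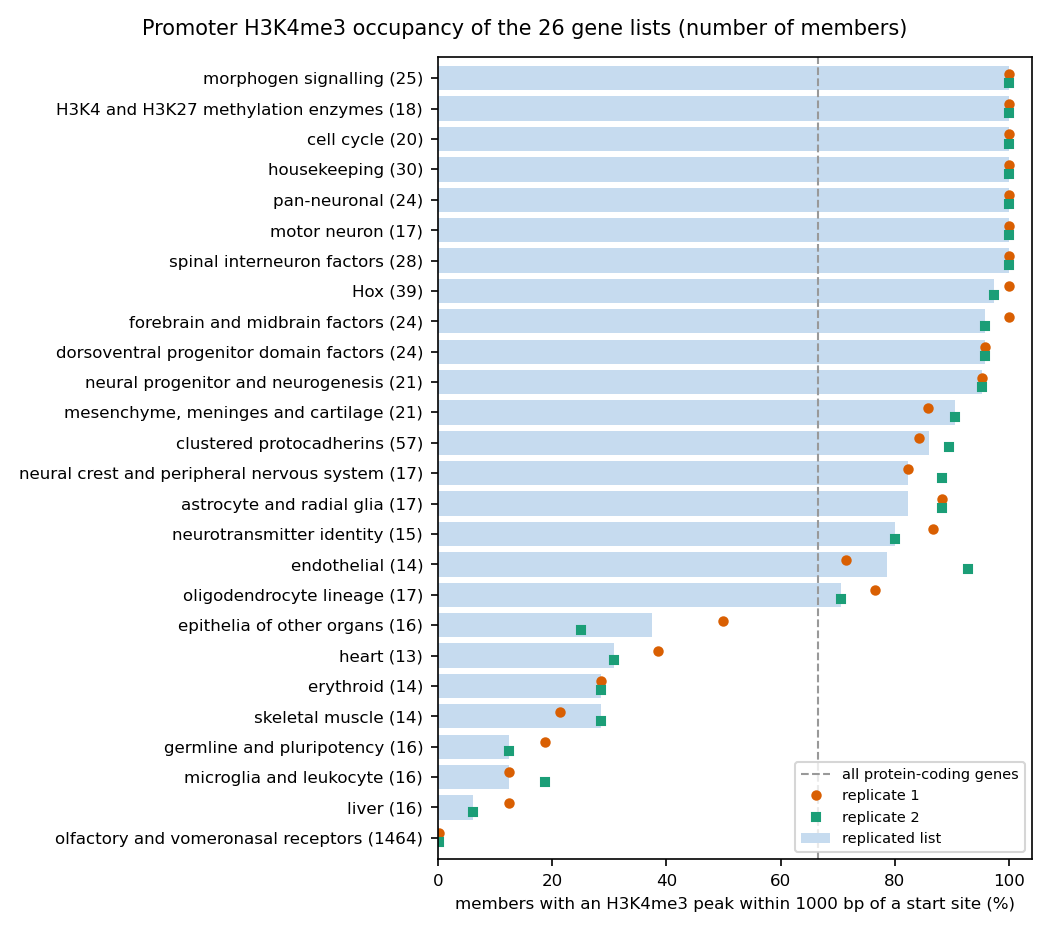
Percentage of the members of each of the 26 gene lists with an H3K4me3 peak within 1000 bp of a start site. Bars show the replicated peak list, circles replicate 1 squares replicate 2 and the dashed line the 66.6% of all protein-coding genes, with neural lists above it and lists of liver, leukocyte and germline genes below it.

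Genes of radial glia and astrocytes had wide domains where they were marked. Of 17 genes of astrocytes and radial glia, 14 were occupied, which did not differ from other genes (adjusted p = 0.23, Fisher's exact test), but their median domain was 5011 bp (5184 and 5516 bp in the libraries, adjusted p = 6.3e-05, permutation test) and 7 were broad (adjusted p = 7.2e-06). The nuclear factor genes Nfib (19755 bp) and Nfia (9762 bp), which act in the onset of gliogenesis, were the widest. The Nfia domain also lay within 1000 bp of a start site of E130114P18Rik. Gfap and Aqp4, markers of differentiated astrocytes, had no replicated promoter peak. In the oligodendrocyte lineage list 12 of 17 were occupied (adjusted p = 0.8) with a median of 2814 bp (2127 and 2729 bp in the libraries, adjusted p = 0.31, permutation test), which passed the test in the pooled list alone (0.042 to 0.69 over 12 alternatives). Pdgfra, the receptor of oligodendrocyte precursors, had 8797 bp and Sox8 had 5558 bp. The myelin gene Mag and Gpr17 had no replicated peak, although Gpr17 had a peak of 239 bp in replicate 1.

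Transcription factors of spinal interneurons included some of the widest domains of protein-coding genes. All 28 were occupied (adjusted p = 7.2e-05, Fisher's exact test), with a median of 4721 bp (3617 and 4170 bp in the libraries, adjusted p = 6.3e-05, permutation test), and 11 were broad (adjusted p = 4.2e-07). Lhx1 lay in a domain of 21645 bp at chromosome 11, 84512465 to 84534109, shared with Aatf, and Lmx1b in one of 17728 bp at chromosome 2, 33629415 to 33647142. The width call ended when peaks were not merged (2635 bp, adjusted p = 0.19, permutation test, with 5.4e-05 to 0.19 over 12 alternatives). Of 24 factors of dorsoventral progenitor domains, 23 were occupied (adjusted p = 0.0029, Fisher's exact test) and Dbx1, a factor of interneuron progenitors, was not, and 6 were broad (adjusted p = 0.002). Irx5 had 12283 bp (11254 ± 713 bp in the libraries, SD, n = 2) and Gbx2 had 8118 bp (6661 and 5707 bp in the libraries). The median of 3323 bp passed the test (adjusted p = 0.01, permutation test), but the medians of 2518 bp in replicate 1 and 2818 bp in replicate 2 did not (adjusted p = 0.51 and 0.15, with 5.4e-05 to 0.79 over 12 alternatives). The call was also lost with −log10 q of at least 10, a signal value of at least 5 or 1 start site per gene, and without merging the width turned direction (2195 bp) and the broad call was lost (adjusted p = 0.61, Fisher's exact test, with 3.5e-05 to 0.61 over 10 alternatives).

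All 17 motor neuron genes were occupied (adjusted p = 0.0029, Fisher's exact test), with a median width of 2878 bp (3095 and 3116 bp in the libraries, adjusted p = 0.2, permutation test), which passed the test in the pooled list and with a gap of 3000 bp (0.00024 to 0.36 over 12 alternatives). Onecut2 had 7705 bp and Isl2, a factor of motor neuron identity, had 7304 bp, with 4713 bp in replicate 1 and 7039 bp in replicate 2. Of 15 genes of neurotransmitter identity, 12 were occupied (adjusted p = 0.43, Fisher's exact test), and 5 of the 12 were broad (adjusted p = 0.00057). Their median width of 2930 bp (1878 and 2739 bp in the libraries) did not pass the test (adjusted p = 0.22, permutation test), but did with a signal value of at least 5, a gap of 3000 bp or CpG-rich genes alone (6e-05 to 0.98 over 12 alternatives). The broad ones included the vesicular transporters for glutamate, Slc17a6 (13676 bp), and for GABA and glycine, Slc32a1 (11594 bp). Slc17a8, another glutamate transporter, and Th, the enzyme of catecholamine synthesis, had no promoter peak.

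Hox genes, which set position along the body axis, had wide domains shared between neighbouring genes. Of 39, 38 were occupied (adjusted p = 3.2e-05, Fisher's exact test), their median domain was 23821 bp (21803 and 24105 bp in the libraries, adjusted p = 6.3e-05, permutation test), and 28 were broad. The 38 genes shared 20 domains, and with each domain counted once the median was 5409 bp (adjusted p = 7.6e-05, permutation test, with 5.4e-05 to 9e-05 over 12 alternatives), near the 5157 bp of pan-neuronal genes, and 50% were broad. A domain of 77718 bp at chromosome 11, 96269140 to 96346857, took in Hoxb3 to Hoxb9 (86562 bp in replicate 1, with Hoxb2, and 77231 bp in replicate 2). A domain of 41134 bp at chromosome 6, 52200093 to 52241226, took in start sites of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9 and Hoxa10. A domain of 26181 bp held start sites of Hoxd3, Hoxd4 and Hoxd8, and one of 21993 bp those of Hoxd9, Hoxd10 and Hoxd11. Another, of 25649 bp, held start sites of Hoxc5, Hoxc9 and Hoxc10. Hoxd3 and Hoxc5 ran past the ends of these domains, and Hoxc6 and Hoxc8 had domains of their own, of 7616 and 4178 bp. The Hoxd3 domain was 14619 bp in replicate 1 and 26168 bp in replicate 2.

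By paralogue group, all 15 genes of groups 5 to 9 were occupied with a median of 41134 bp (39134 and 40789 bp in the libraries) and a median signal value of 36.8. All 12 of groups 1 to 4 had a median of 14448 bp (14097 and 12615 bp) and a signal value of 37.7. Of the 12 genes of groups 10 to 13, 11 were occupied, with 6322 bp (5239.5 and 6171 bp) and a signal value of 14.9. Hoxd12 had no replicated peak but a peak of 288 bp in replicate 1. Neighbouring genes share domains, so these genes are not independent and no test was made between the groups. A gene took its widest domain and highest signal value at any start site, which can lie beside a gene of another group. Hoxa3, of groups 1 to 4, was counted at 41134 bp and 53.3 from the domain of Hoxa5 to Hoxa10. Hoxc5, of groups 5 to 9, was counted at 25649 bp and 25.4 from that of Hoxc9 and Hoxc10. With each domain counted once the medians were 7005, 25649 and 5409 bp for groups 1 to 4, 5 to 9 and 10 to 13. With each gene counted the difference in width between the groups exceeded that between the libraries, but groups 10 to 13 were the wider of groups 1 to 4 and 10 to 13 with a gap of 3000 bp (49489 against 36936 bp), with a gap of 0 bp or −log10 q of at least 10 (4496 against 4411 bp) and with a signal value of at least 5 (5058 against 4411 bp).

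**Figure D2:**
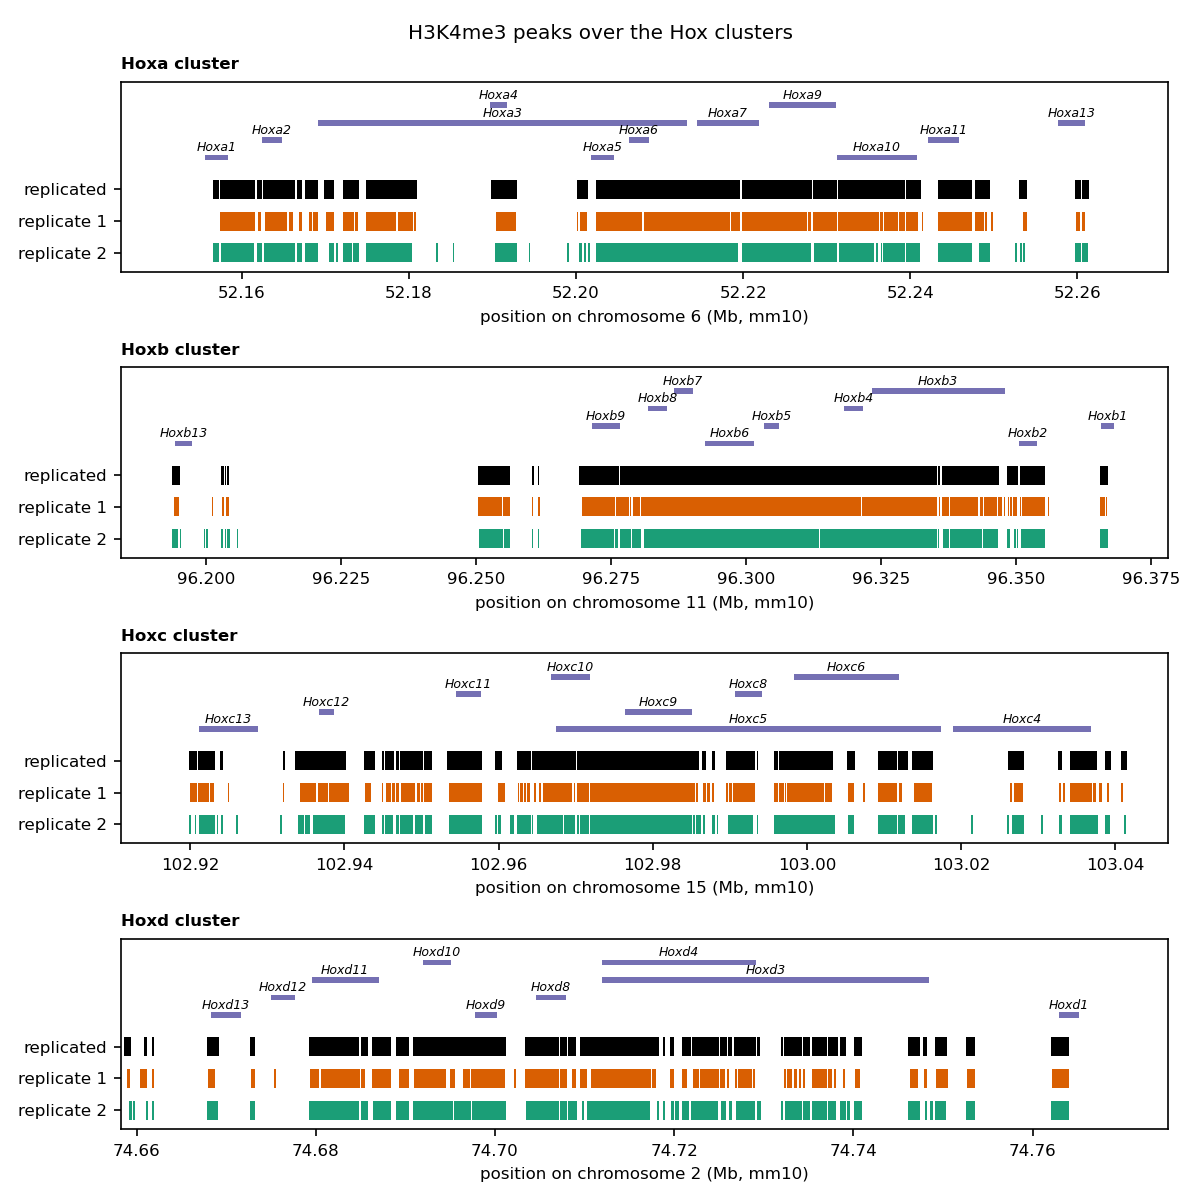
Maps of the 4 Hox clusters on mm10, with position in Mb on the horizontal axes, gene bodies in purple and H3K4me3 peaks of the replicated list (black), replicate 1 (orange) and replicate 2 (green) as blocks. Nearly unbroken peaks run from Hoxb3 to Hoxb9.

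Factors of the forebrain and midbrain were mostly marked, by narrow domains. Of 24, 23 were occupied (adjusted p = 0.0029, Fisher's exact test), but their median domain was 1607 bp (1065 and 1653 bp in the libraries), narrower than that of random lists (adjusted p = 0.0025, permutation test), and the median signal value was 9.06 against 47.9 for all marked genes. Neurod6 had 5634 bp and Satb2 4644 bp. Otx2, a factor of forebrain and midbrain, had no replicated peak and a peak of 237 bp in replicate 1. With peaks of signal value 5 or more, 66.7% were occupied (adjusted p = 1, Fisher's exact test), and with a gap of 3000 bp the median width was 2383 bp (adjusted p = 0.77, permutation test). The occupancy call was also lost with −log10 q of at least 10 and with 1 start site per gene. Among CpG-rich genes alone the occupancy lay below that of other genes, without a call. There 99.1% of all genes were marked, so a list had almost no room to be higher. Over the alternatives the adjusted p ran from 0.00027 to 1 for occupancy (exact test) and from 6e-05 to 0.77 for width (permutation test).

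The clustered protocadherins, neuronal adhesion genes with many alternative promoters, were occupied in 49 of 57 (adjusted p = 0.0029, Fisher's exact test), with narrow domains of 878 bp (670 and 790 bp in the libraries, adjusted p = 6.3e-05, permutation test) and a median signal value of 4.76. Among CpG-rich genes alone the width turned direction, to a median of 4351 bp (adjusted p = 0.05, permutation test, with 5.4e-05 to 0.05 over 12 alternatives). Pcdhgc4 and Pcdhgc5 shared the widest, of 6481 bp, Pcdha8 had none and Pcdhb10 only a peak of 551 bp in replicate 2. With peaks of signal value 5 or more the occupancy was 40.4%, below that of other genes (adjusted p = 0.00059, Fisher's exact test, with 7.5e-08 to 1 over 9 alternatives).

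**Figure D3:**
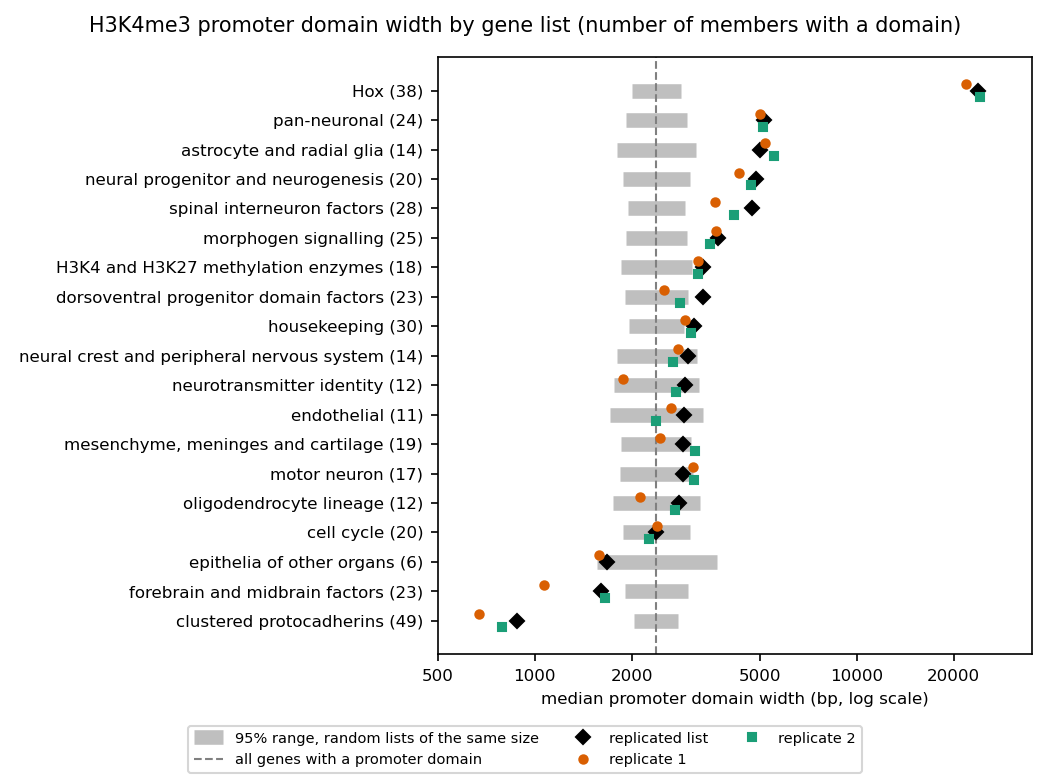
Median width of the H3K4me3 promoter domain, in bp on a log scale, for each list with at least 5 occupied members. Diamonds show the replicated list, circles replicate 1, squares replicate 2, grey bars the 95% range of random lists of the same size and the dashed line the 2382 bp of all marked genes, with Hox genes at 23821 bp and clustered protocadherins at 878 bp.

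Lists of tissues that adjoin or enter the neural tube varied. Of 21 genes of mesenchyme, meninges and cartilage, 19 were occupied (adjusted p = 0.025, Fisher's exact test), while Lum and Meox1 were not. Among the 19 were Foxc1 with 6640 bp and Foxc2 with 6077 bp (4126 and 6039 bp in the libraries). The call was lost in 5 of 9 alternatives, in replicate 1 alone (85.7%, adjusted p = 0.088, Fisher's exact test), with −log10 q of at least 10, a signal value of at least 5, 1 start site per gene or CpG-rich genes only (0.024 to 1 over the 9). Of 17 genes of neural crest and peripheral nerve, 14 were occupied (adjusted p = 0.23, Fisher's exact test). They were led by Tfap2a with 7491 bp (8045 and 11043 bp in the libraries) and Tfap2b with 6405 bp. Dbh had no peak and Phox2b only a peak of 202 bp in replicate 2. Of 14 endothelial genes, 11 were occupied (adjusted p = 0.43, Fisher's exact test), led by Esam with 4526 bp and Egfl7 with 4431 bp (2773 bp in replicate 1 and 4365 bp in replicate 2). The Egfl7 domain also lay within 1000 bp of a start site of Gm20532. There was no peak at Tek and only a peak of 773 bp in replicate 2 at Emcn. The median widths of these 3 lists did not pass the test in the replicated list (adjusted p from 0.17 to 0.27, permutation tests), but that of mesenchyme did in the pooled list and in replicate 2 alone (adjusted p = 0.042 and 0.036, with 0.036 to 0.68 over 12 alternatives).

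Genes of other organs and lineages were marked less often than all other protein-coding genes, and the p-values are from Fisher's exact test. The comparison does not separate lineage from CpG content, since only 32.4% of genes that are not CpG-rich were marked. Erythroid, skeletal muscle, heart and other epithelial genes (28.6% to 37.5%) lay near that share. Liver, leukocyte, germline and receptor genes lay below it. Among CpG-rich genes alone, where few members were left, only the germline list was called lower. Among 16 liver genes only Trf, a transferrin gene, was occupied (adjusted exact p = 1e-05), and Afp and Ahsg were not. Of 16 genes of microglia and leukocytes, Hexb and Fcgr3 were occupied (adjusted exact p = 5.3e-05), with none at Aif1 and C1qa. Of 16 germline and pluripotency genes, Dazl and Tdrd1 were (adjusted exact p = 5.3e-05), with no peak at Ddx4 and only a peak of 307 bp in replicate 1 at Dppa3. In erythroid genes 4 of 14 were occupied (adjusted exact p = 0.011), led by Tal1 and Epor, with none at Alas2 and Ermap. In skeletal muscle genes it was 4 of 14 (adjusted exact p = 0.011), led by Myod1 and Ckm, with none at Acta1 and Actc1. In heart genes it was 4 of 13 (adjusted exact p = 0.019), led by Tbx20 and Gata4, with no peak at Myh6 and only a peak of 1354 bp in replicate 1 at Hand1. In genes of other epithelia it was 6 of 16 (adjusted exact p = 0.037), led by Sftpc and Krt10, with none at Ins2 and Krt14. The Sftpc and Krt10 domains lay over 1000 bp from the outermost start of the gene and counted through another annotated start site. They ended at 70521360 and 99387437, against outermost starts at 70524081 and 99389364. In replicate 1 alone heart and other epithelia lost the call, with 38.5% of heart genes and 8 of the 16 epithelial genes occupied (adjusted exact p = 0.054 and 0.21, with 9.7e-05 to 1 and 0.0016 to 1 over 9 alternatives). Marked members of these lists had low median signal values, from 4.75 for heart to 27.5 for microglia and leukocytes. The median for all marked genes was 47.9. Of 1464 olfactory and vomeronasal receptor genes, 4 were occupied (0.273%, odds ratio 0.0011, with a p too small to represent), including Olfr94 and Vmn1r4, the last sharing its domain with Nt5c3, and Olfr1 and Olfr10 were not.

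Housekeeping and cell cycle genes were marked without exception. All 30 housekeeping genes were occupied (adjusted p = 4.2e-05, Fisher's exact test), with a median of 3131 bp (2937 and 3066 bp in the libraries, adjusted p = 0.013, permutation test). Rpl13a had the widest domain at 7078 bp, which was 3045 bp in replicate 1 and 6977 bp in replicate 2. That domain also lay within 1000 bp of a start site of Rps11. Ywhaz had 5838 bp (4724 and 4154 bp in the libraries). All 20 cell cycle genes were occupied (adjusted p = 0.0012), with 7328 bp at Ccnd2 and 6184 bp at Ccnd1 and a median width of 2373 bp (adjusted p = 0.96, permutation test). All 25 morphogen signalling genes were occupied (adjusted p = 0.00018) with a median of 3718 bp (3647 and 3496 bp in the libraries, adjusted p = 0.00038, permutation test). The widest were at Ptch1, the Hedgehog receptor, with 14475 bp and Wnt7b with 7433 bp, which was 3284 and 3420 bp in the libraries. All 18 genes of H3K4 and H3K27 methylation enzymes were occupied (adjusted p = 0.0019), with a median of 3336 bp (adjusted p = 0.018, permutation test). Setd1b had 14767 bp (11706 and 14677 bp in the libraries), in a domain that also lay within 1000 bp of a start site of Rhof. Kdm6b had 13708 bp. The width calls of housekeeping genes and of methylation enzymes were lost when only CpG-rich genes were used (adjusted p = 0.057 for both, permutation tests, with 0.0082 to 0.089 and 0.012 to 0.057 over 12 alternatives). The first was also lost with 1 start site per gene and with a gap of 0 bp, and the second with a gap of 3000 bp. The broad share of 5 of 25 morphogen genes (adjusted p = 0.017, Fisher's exact test) was not past the threshold in either library alone (adjusted exact p = 0.075 and 0.068, with 0.0029 to 0.075 over 10 alternatives).

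**Figure D4:**
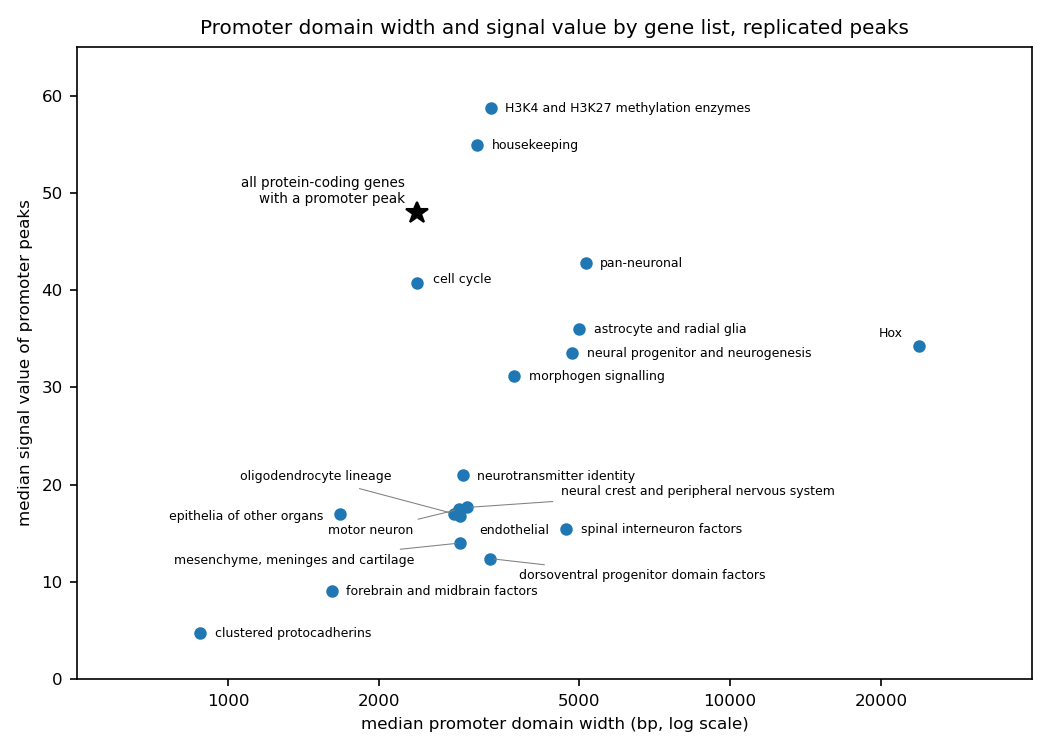
Median promoter domain width in bp (horizontal axis, log scale) against the median signal value of promoter peaks (vertical axis) for each gene list in the replicated peaks, with the star at all marked protein-coding genes (2382 bp and 47.9). Factors of dorsoventral progenitor domains and of spinal interneurons have low signal values, 12.4 and 15.4.

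Outside the lists, the 10 widest promoter domains held, besides Hox genes and Lhx1 and Nfib, the factor genes Ebf3 with 23506 bp, Pou3f3 with 20547 bp and Tshz1, which shared 18310 bp with Zadh2. Pou3f3 had 21091 bp in replicate 1 and 14312 bp in replicate 2. Peaks far from any annotated start site were fewer and weaker: 3060 replicated peaks (12.2%) lay over 10000 bp from one, with a median signal value of 5.26. The 5 with the highest signal value were at chromosome 12, 8640074 to 8641763 (61.0, intergenic, nearest gene Pum2, 32371 bp away, 55.6% repeat sequence), chromosome 9, 32031477 to 32034651 (57.1, intergenic, nearest the pseudogene Gm47481), chromosome 1, 165280716 to 165284488 (56.4, intergenic, 11301 bp from Gpr161), chromosome 9, 67631394 to 67634749 (54.9, intergenic, nearest the pseudogene Gm47110) and chromosome 19, 7163905 to 7166755 (53.8, an intron of Macrod1, nearest start site Otub1).

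The list calls of occupancy rest on comparison with all protein-coding genes. Among CpG-rich genes, where 99.1% were marked, 0 lists were higher and 1, the germline list, was lower.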

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

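The addition of RefSeq start sites and the count of each domain once in the Hox groups were chosen only after the results were seen. The cause of each shift below was not tested unless the alternative's own construction shows it. Occupied protein-coding genes numbered 13833 to 14828, lists with wider domains 6 to 12 and lists with more broad domains 8 to 11. Over single lists, 203 occupancy values, 201 widths and 178 broad shares had the same outcome as in the main analysis. These counts include values called in neither setting, so they do not measure how often a call was kept. A call was lost by 21, 12 and 5 values and gained by 8 widths and 3 broad shares. Another 9 occupancy values and 2 widths turned direction, counted only where either setting gave a call.

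Shared peaks were 97.8% and 94.8% (replicates 1 and 2) for −log10 q of at least 10 and 96.4% and 94.9% for a signal value of at least 5, and 82.0% and 79.5% for an overlap of 50% of the peak and 74.7% and 74.4% for 50% of both. The share at promoters was 76.2% with −log10 q of at least 10, 80.1% with a signal value of at least 5, 59.4% in the pooled list, 61.6% to 62.1% with 1 library left out, 64.2% and 76.2% with windows of 500 and 2500 bp, 57.6% with 1 start site per gene and 70.9% with RefSeq start sites added.

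Hox widths moved with the merging gap by construction: groups 1 to 4, 5 to 9 and 10 to 13 had medians of 4411, 15929 and 4496 bp at a gap of 0 bp and 36936, 84362 and 49489 bp at 3000 bp. They were 4411, 38869 and 4496 bp with −log10 q of at least 10, and 4411, 38869 and 5058 bp with a signal value of at least 5. In the pooled list groups 1 to 4 and 10 to 13 had 30978.5 and 5584.5 bp, and groups 10 to 13 had 5409 bp with the 2500 bp window. With each domain counted once they had 7005, 25649 and 5409 bp. With 1 library left out the ranges were 12615 to 14097, 39134 to 40789 and 5239.5 to 6171 bp.

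With CpG-rich genes alone, 0 lists were higher and 1 lower in occupancy, against 13 and 8, as nearly all such genes are marked. There occupancy was 95% for dorsoventral factors, 94.7% for forebrain and midbrain factors, and 100% for leukocyte, erythroid, heart, other epithelia and olfactory receptor genes, with few members left, while the liver list had no such member and gave no value, and protocadherin domains had a median of 4351 bp. Clustered protocadherins were occupied in 54.4% with −log10 q of at least 10 and 40.4% with a signal value of at least 5. Dorsoventral factors had a median width of 2195 bp at a gap of 0 bp. Lists with narrower domains numbered 2, and were 5 with the 2500 bp window, 1 with the 3000 bp gap and 1 with CpG-rich genes. No paired analysis was possible because there is 1 group. Read depth is unknown, so the weakest peaks, which differed most between the libraries, cannot be set against it.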

Other observations

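The repeat test of far peaks and the germline test were chosen after the results were seen, and genes named here outside the rule for named genes were chosen after their values were seen. The shares of marked genes by type were not tested against each other. A replicated peak lay at 923 of 5854 lincRNA genes (15.8%), 1077 of 2959 antisense genes (36.4%), 326 of 2202 microRNA genes (14.8%) and 208 of 9940 processed pseudogenes (2.09%), with 16.1% and 36.3% for lincRNA and antisense genes in replicate 1 and 16.1% and 36.6% in replicate 2. Marked antisense genes had a median domain of 2478 bp, near the 2382 bp of protein-coding genes. Peaks that also lay near a start site of a protein-coding gene were not removed from these counts. The shares and widths thus do not separate marking of these genes from marking of protein-coding neighbours.

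In lists of other organs and lineages some marked members shared their domain with another gene, both having a start site within 1000 bp of it: Ckm with Klc3, Nphs1 with Kirrel2, Sftpc with Bmp1, Trf with Gm20425 and Vmn1r4 with Nt5c3. Across all protein-coding genes with a promoter domain, 21.8% shared it with another protein-coding gene.

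Dorsoventral progenitor and spinal interneuron factors had low promoter signal, as did other lists, such as clustered protocadherins (4.76), forebrain and midbrain factors (9.06) and endothelial genes (16.8). Their 51 marked genes had a median signal value of 13.4 against 47.9 for all marked genes (11.0 against 40.8 in replicate 1, 12.3 against 42.4 in replicate 2). Width did not account for it, since 10000 random lists matched on width had medians from 42.9 to 51.9 (95% range), and neither did CpG content, with 42.2 to 51.9 for lists matched on the CpG ratio. Taking the highest signal over the whole domain gave 13.5, below the 41.3 to 52.5 of random lists, so a summit outside the window did not account for it either. No biological explanation was tested, since the design holds 1 group.

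CpG-rich promoters without a peak numbered 103 of 11242. Sequence shared between gene copies may account for part of them: in 53 (51.5%) most 31-base words within 500 bp of the CpG-rich start sites occurred again on the assembled chromosomes, against 0.772% of the 11139 marked genes. Tmem254a, Plac9a and Entpd4 are among the 53. Among single-copy CpG-rich genes, 4 of the 6 members of the germline and pluripotency list lacked a peak, Ddx4, Mael, Sycp1 and Sycp3, against 0.415% of other genes (Fisher's exact test, two-sided, p = 5.4e-09). The same members had already been seen to be low among CpG-rich genes, so this test decides nothing and a germline explanation stays open. The meiosis genes Spo11, Hormad1 and Sycp2 were also among the 50 unmarked. The neural factors Otx2, Dbx1 and Nr2e1 were among the 50 too, but they do not describe the rest. Most of the 50 were in none of the gene lists, such as Asz1, Mov10l1, Msh4, Stk31 and Tex12, and were not sorted by kind. The germline and pluripotency list held only 16 genes, so absence from it does not show that a gene is not a germline gene. Which of the 50 are silenced is not tested by peak lists.

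Strong peaks far from annotated start sites were few: 222 of the 3060 far peaks had a signal value at or above the list's median of 23.1. Start sites missing from the annotation could account for some, since 26.6% of these lay within 1000 bp of a RefSeq transcript start, against 9.20% of weaker far peaks, and 4 of the 5 named ones did, all but the chromosome 12 peak. The share lay between the bounds of 10% and 50% set before the test, so most strong far peaks stay open. Repeat sequence made up a median of 11.0% of strong far peaks and 10.1% of promoter peaks, so repeats did not set the typical strong far peak apart. The share lay between the bounds of that test, which were set after the results were seen. The medians decide nothing about single peaks, such as the chromosome 12 peak with 55.6% repeat sequence. No biological explanation was tested.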
